A study of Homo sapiens with 4 samples.

How the data were processed

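Gene expression was measured on Affymetrix 3-prime arrays in HCC1806, an established human triple-negative breast cancer cell line, after treatment with docetaxel or with DMSO, its solvent control. Docetaxel is a taxane that binds and stabilises microtubules. There were 4 arrays, 2 with cells given 6.4 µM docetaxel for 6 h and 2 with cells given DMSO. No time was recorded here for the DMSO cells, so a control matched in time cannot be assumed. The sample titles call the control cells untreated and the descriptions say DMSO, and the second reading is used here. Total RNA was labelled with biotin, per the labels.

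The deposited values are log2 expression levels per probe set, 1 column per array. The submitters' processing notes name RMA, Affymetrix Expression Console and Partek 6.4, without the role or order of each. RMA corrects background, normalises between arrays and summarises the probes of a probe set, and its levels compress large differences. The deposited log2 values still differed in their medians between arrays, so the arrays had not been forced to 1 distribution after summarisation. The test used by the submitters is not given in the sources used here.

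The table holds 54675 probe sets, of which 62 are Affymetrix controls. Among the others, 41091 had 1 gene symbol in the platform's annotation, 1801 had several and 11721 were not listed with a gene. Of the probe sets with 1 symbol, 41043 were matched by gene ID to a RefSeq gene table of assembly GRCh38.p14, used for names alone, and 0 symbols changed. Each gene was represented by the probe set with the highest mean over the 4 arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. No filter on dim probe sets was applied. Genome positions are not given because the values name no genome build.

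Docetaxel was compared with DMSO in limma 3.58.1 under R 4.3.3, with lmFit and eBayes at default settings, no block and 2-sided p-values. Adjustment was by Benjamini-Hochberg over all 19775 genes, with a threshold of 0.05. A log2 change is docetaxel minus DMSO and carries the moderated standard error (SE). The fit had 2 residual and 3.85 prior degrees of freedom. Rose and fell refer to genes past this threshold. Values per group are means of 2 arrays, and nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, with a median SE of 0.076 on the log2 scale.

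Before the data were examined, 27 gene lists were fixed, and each was tested with limma's camera at its preset correlation of 0.01 against all tested genes, with Benjamini-Hochberg adjustment over the 27 lists. Camera's direction is relative to all genes, whose levels fell on balance, so a list with a median below 0 can be placed higher. Camera with an estimated correlation and fry were run beside it. In fry, the directional p tests whether the genes of a list move one way on balance and the mixed p whether they change in either direction. Neither compares the list with other genes.

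The genes named were also chosen by a rule fixed before the data were examined. The first part takes the 12 largest rises and the 12 largest falls past the threshold, where both docetaxel arrays lay beyond both DMSO arrays and the higher group mean was above the median level of all genes, 7.24. The second part takes from each list up to 4 members past the threshold with the largest changes, or, with none past it, the 2 largest above the median level. The alpha- and beta-tubulin genes are given member by member, and the ACTB and GAPDH control probe sets are given for RNA quality. Genes named outside this rule are said to be so.

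The alternatives fixed in advance changed the normalisation (quantile, or each array centred on its median), the choice of probe sets, the filter on dim genes, the variance model, the threshold, the replicate block and the set test, and left out each array in turn. The filter on dim genes kept a gene if either group mean was above the median level of all genes. A gene could thus be kept through its change. Another 3 alternatives were chosen after seeing the data. The first centred each array on its 18 hybridisation spike-in probe sets (bioB, bioC, bioD and cre). An earlier version used only the 9 probe sets of the r2 design, and the set was widened after the shift of those 9 had been seen but before any count of genes from either. Both versions were run and are given. The third set each list's median against 10000 random lists matched on mean level in 50 bins, which ignores correlation between genes. In all, 17 alternatives gave counts of genes, 2 of them chosen after seeing the data, and 3 more, beside the matched lists, applied to gene lists alone.

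The fit was tested on simulated data for docetaxel against DMSO with 19775 genes. In these, 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, in both directions. The noise was independent between genes, and no offset between arrays was added. The fit recovered 67.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 97.0% of those changed 4-fold, and called 13 unchanged genes. The data differ from this setting, with 8639 genes called and an offset between arrays, so these rates do not carry over to the counts below.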

Results

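The series asks which early changes docetaxel induces in HCC1806 cells, with 2 arrays of cells given 6.4 µM docetaxel for 6 h and 2 arrays of cells given DMSO. The array medians over all probe sets were 6.179 and 6.215 in DMSO and 6.134 and 6.126 with docetaxel, on the log2 scale of the deposited RMA levels. Arrays of the same group correlated at r = 0.9976 (DMSO) and r = 0.9977 (docetaxel) across probe sets, which are not independent replicates. Between groups r was 0.9851 to 0.9854. The SD of the log2 difference was 0.164 to 0.170 within groups and 0.420 to 0.427 between groups.

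After docetaxel, the membrane mucin MUC4, the cornified envelope precursor SPRR1A, the AP-1 subunit FOSB and the collagenase MMP13 rose 7.42-fold (MMP13), 7.34-fold (FOSB), 7.85-fold (SPRR1A) and 8.29-fold (MUC4). MMP13 and FOSB were dim in DMSO, at mean levels of 5.67 and 6.08, which leaves the size of their rises less certain. The cadherin CDH10 fell 9.0-fold, the transcription factors MYBL1 and SOX2 fell 7.31-fold and 6.18-fold, and the receptor tyrosine kinase KIT fell 5.16-fold. In all, 2299 genes rose and 6340 fell, and of these 275 rose and 669 fell at least 2-fold. The 2-fold counts were 436 higher and 402 lower after quantile normalisation, 381 and 482 after median centring, 441 and 414 after centring on 18 spike-in probe sets and 456 and 395 after centring on 9 of them. Genes that fell made up 73.4% of the called genes. That share depends on the scaling. It was 50.2% after quantile normalisation and 56.1% with each array centred on its median. Both make the arrays alike by construction, in distribution or in median. They would also remove a real broad fall, so these 2 shares cannot decide whether the excess was real. The share was 45.1% with each array centred on the 18 spike-in probe sets, a scaling chosen after seeing the data. With only the 9 of the r2 design it was 41.7%. The median log2 change of all genes was -0.11 as deposited, 0.0077 after quantile normalisation, 0.0065 after median centring and 0.068 or 0.089 after the spike-in centrings.

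Among the 12 largest rises, the log2 change of MUC4 was 3.05 ± 0.079 (SE, n = 2 arrays per group; limma adjusted p = 7.61e-05), from a mean level of 8.01 to 11.1. STEAP4, a metalloreductase, rose by 3.08 ± 0.15 from 4.47, a level near background that leaves the size of the change uncertain, RUNDC3B by 2.96 ± 0.072, TFPI, an inhibitor of the tissue factor pathway, by 2.86 ± 0.073 and IL1RL1, the receptor of interleukin-33, by 2.84 ± 0.069. PAPPA, a protease of insulin-like growth factor binding proteins, CLIC3, PLAT, the tissue plasminogen activator, and MYADM rose by 2.45 (MYADM) to 2.53 (PAPPA). RUNDC3B and CLIC3 were also dim in DMSO, at mean levels of 5.92 and 5.39. The largest fall was that of CDH10, -3.17 ± 0.15 (SE; limma adjusted p = 9.13e-05). SLC16A14, CCDC15, NAP1L2, CDC45, PRIM1, a DNA primase subunit, MND1, TCF19 and MNS1 changed by -2.19 (MNS1) to -2.61 (SLC16A14). Of these 24 genes, 13 had 1 probe set, and all 24 kept their direction and their call under every alternative in which they were tested. PLAT, CDH10, SLC16A14, KIT and CDC45 were read by an _s_at probe set alone, so they were not tested without _x_at and _s_at probe sets. A dimmer probe set of MYBL1 went the other way, with a log2 change of 0.23. With the mean of a gene's probe sets the log2 changes were smaller for several of them, among them MUC4 (1.49), IL1RL1 (1.41), SPRR1A (1.72), STEAP4 (1.80), PAPPA (0.89), MYBL1 (-0.85) and SOX2 (-0.95).

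**Figure D1:**
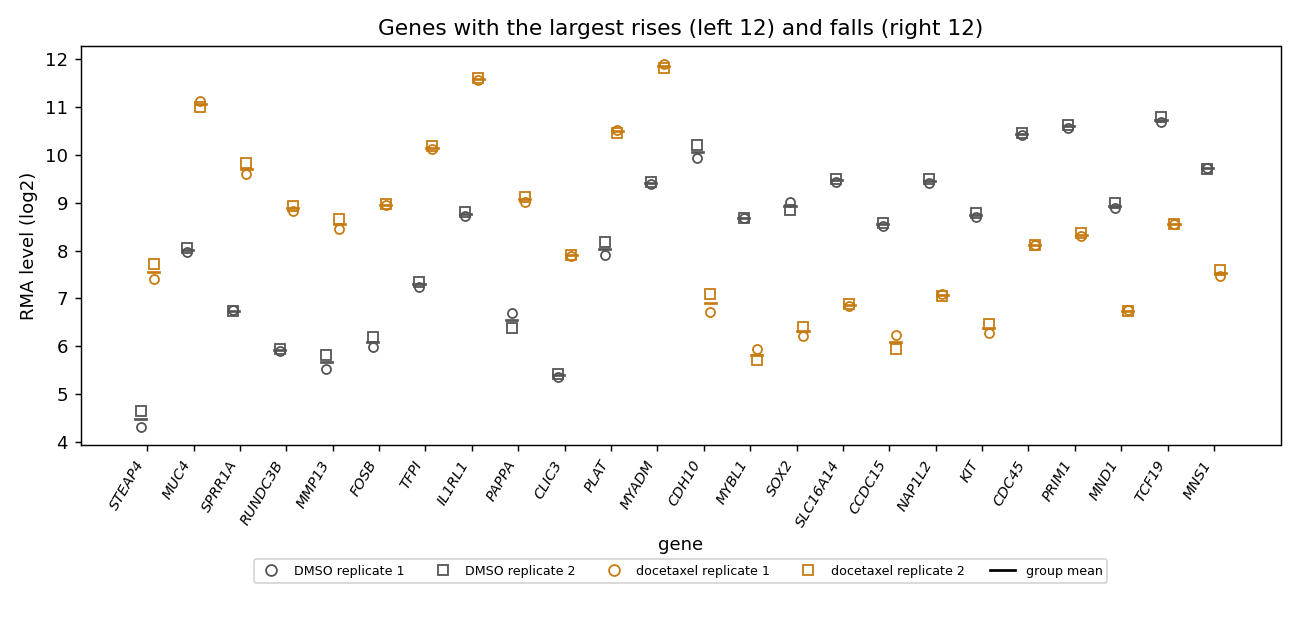
RMA level (log2, vertical axis) of the 12 genes with the largest rises and the 12 with the largest falls (horizontal axis) on each of the 4 arrays, with a bar at each group mean. For MUC4 the group means were 8.01 (DMSO) and 11.1 (docetaxel). In all 24 genes both docetaxel arrays lay on the same side of both DMSO arrays, which the rule for choosing them required.

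Genes of mitosis and of DNA replication fell together. All 38 measured members of the G2/M and mitosis list fell, with a median log2 change of -1.12, and so did 29 of the 30 members of the G1/S and DNA replication list, with a median of -1.39. The mitotic spindle factor HMMR fell by 1.82 ± 0.072, the checkpoint kinase BUB1 by 1.61 ± 0.064, the transcription factor FOXM1 by 1.61 ± 0.072 and the topoisomerase TOP2A by 1.57 ± 0.068 (log2 ± SE, n = 2 per group). BUB1 was at -0.83 with the mean of its probe sets. In the replication list, CDC45 and MCM10, which help start replication forks, fell by 2.31 ± 0.066 and 1.94 ± 0.079, ORC1 of the origin recognition complex by 2.07 ± 0.082 and E2F8 by 1.95 ± 0.083. The exception was the cyclin CCND1, chosen after its value was seen, which rose by 0.40. These counts were the same adjusted over the list alone and under every scaling. Camera's adjusted p was 4.88e-15 for mitosis and 7.83e-13 for replication. For each of these lists, adjusted p = 0.54 with an estimated correlation.

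Alpha- and beta-tubulin genes, whose proteins are the target of docetaxel, went in both directions. TUBA1A rose 3.58-fold (log2 1.84 ± 0.065), TUBB2A rose 1.97-fold (0.98 ± 0.070), and the dimmer TUBB2B and TUBB4A rose by 0.67 ± 0.16 and 0.57 ± 0.15. The abundant TUBB fell 1.73-fold (-0.79 ± 0.068), TUBA4A fell 1.59-fold, TUBA1B fell by 0.44 ± 0.069 and TUBA1C by 0.35 ± 0.069. The other 5 of the 13 measured genes were not past the threshold, with log2 changes of -0.19 (TUBA8), -0.093 (TUBB3), 0.073 (TUBB6), -0.063 (TUBB4B) and -0.027 (TUBB1). The counts were 4 higher and 4 lower, also adjusted over the list alone. The list's median was -0.063, its mean 0.12 and camera placed it higher at an adjusted p of 0.423; its median was 0.18 after quantile normalisation. Under quantile normalisation TUBB3, TUBB4B and TUBB6 were called higher, at 0.18, 0.21 and 0.33, and TUBA1C, at -0.14, was not called. TUBB6 was also called higher after either spike-in centring (0.25 and 0.27), and after centring on the r2 spike-ins TUBB1 was called higher at 0.17 and TUBA1C, at -0.16, was not called. Without DMSO replicate 1, TUBB4A was not called (adjusted p = 0.126) and TUBA8 was called lower at -0.33, and without DMSO replicate 2 TUBB4A was not called either (adjusted p = 0.154). TUBB, TUBA1B, TUBA1C, TUBB2B, TUBB3 and TUBB4B were read by _x_at probe sets, a class that can bind several members of a family, and TUBA1A by an _s_at probe set. Without these 2 classes TUBA1B was not called (adjusted p = 0.0504), and TUBA1A, TUBA1C, TUBB2B, TUBB3 and TUBB4B could not be tested.

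**Figure D2:**
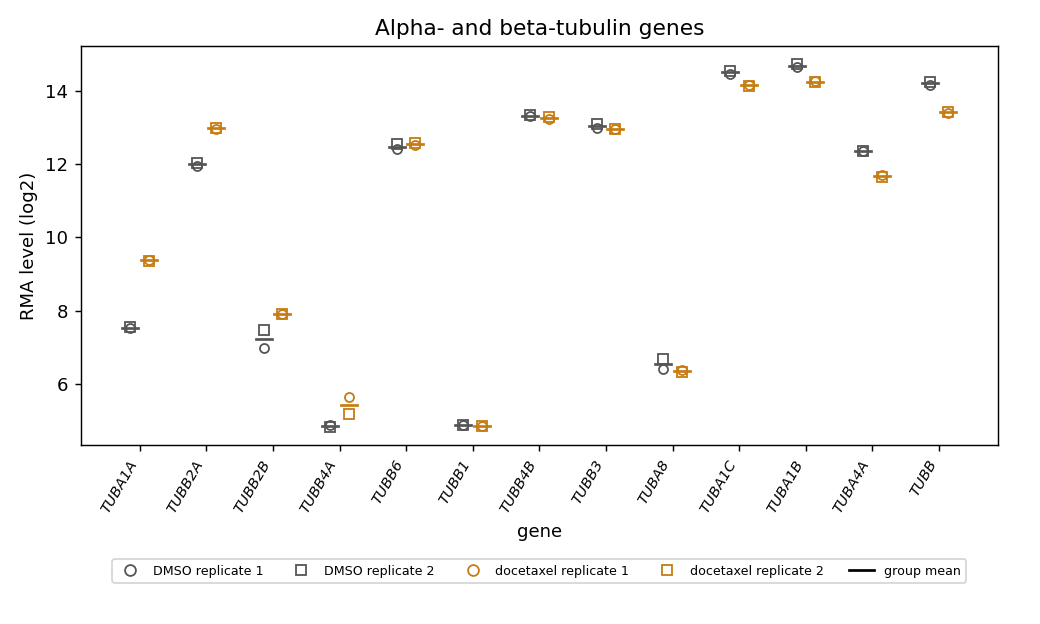
RMA level (log2, vertical axis) of the 13 measured alpha- and beta-tubulin genes (horizontal axis) on each of the 4 arrays, with a bar at each group mean, ordered by log2 change. TUBA1A went from a mean of 7.54 to 9.38 and TUBB from 14.2 to 13.4, while TUBB6 did not pass the threshold as deposited and was called higher after quantile normalisation and either spike-in centring.

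Of 20 measured genes for tubulin folding, modification and autoregulation, 13 fell and 4 rose (14 and 4 adjusted over the list alone), and under the other scalings 8 to 11 were lower and 4 to 5 higher. TUBG1, the gamma-tubulin of the centrosome, fell by 1.34 ± 0.067, the tubulin tyrosine carboxypeptidase VASH2 by 1.32 ± 0.072, the tubulin tyrosine ligase TTL by 1.17 ± 0.071 and TUBD1 by 0.81 ± 0.078. VASH2 was below the median level of all genes in both groups, at means of 6.73 in DMSO and 5.41 with docetaxel. The list's median was -0.36 and its camera adjusted p 0.100. It passed the threshold with the mean of a gene's probe sets (adjusted p = 0.0319), with a variance trend (0.0470), after spike-in centring (0.0473, or 0.0401 with the r2 set) and in fry's directional test (0.0142). TTL was at -0.66 with the mean of its probe sets and was not called without _x_at and _s_at probe sets, at -0.13. Of 24 microtubule-associated proteins 15 fell and 0 rose (16 and 1 adjusted over the list alone), with a median of -0.28 and a camera adjusted p of 0.0067. For this list, adjusted p = 0.59 with an estimated correlation. The spindle assembly factor TPX2 fell by 1.15 ± 0.071, the depolymerising kinesin KIF2C by 0.97 ± 0.082, CLASP1 by 0.88 ± 0.064 and stathmin (STMN1) by 0.76 ± 0.073. With the mean of its probe sets CLASP1 was at -0.31. The list was not past the threshold without _x_at and _s_at probe sets (adjusted p = 0.0784), among genes above the median level (adjusted p = 0.0763) or against random lists matched on level (adjusted p = 0.207), and 1 to 2 of its members were called higher and 8 to 9 lower after the other scalings.

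Most sterol genes and stress-response genes rose. In the sterol synthesis and uptake list 12 of 16 members rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 change of 0.80. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, rose 4.07-fold (2.03 ± 0.096) and HMGCS1, an enzyme of the mevalonate pathway, rose 4.01-fold (2.01 ± 0.077), with MSMO1 at 1.74 ± 0.077 and the sterol carrier STARD4 at 1.55 ± 0.068. In the unfolded protein and integrated stress response list, 16 of 23 members rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.52. The glutathione-degrading enzyme CHAC1 rose by 2.00 ± 0.067, the mTORC1 inhibitor DDIT4 by 1.51 ± 0.065, asparagine synthetase (ASNS) by 1.35 ± 0.070 and VLDLR by 1.34 ± 0.12. VLDLR was dim, at mean levels of 5.07 in DMSO and 6.40 with docetaxel, so the size of its rise is less certain. ASNS was at 0.51 without _x_at and _s_at probe sets. The members that fell, SDF2L1 (-0.65) and HSP90B1 (-0.37), chosen after their values were seen, are chaperone components of the endoplasmic reticulum. Camera's adjusted p was 4.49e-10 for sterol genes and 2.71e-09 for the stress response. Both lists had adjusted p = 0.54 with an estimated correlation.

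Many immediate early genes and NF-kappaB targets also rose. Of 25 immediate early and AP-1 genes 17 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 0.47. FOSB rose by 2.88 ± 0.090, ATF3 by 2.00 ± 0.068, the phosphatase DUSP5 by 0.99 ± 0.077 and FOS by 0.94 ± 0.065, while EGR1 (-0.54) and IER5 (-0.24), chosen after their values were seen, fell. Of 26 NF-kappaB targets and cytokines 13 rose and 1, the cytokine IL6 (-0.51, likewise chosen after its value was seen), fell, also adjusted over the list alone, with a median of 0.32. The chemokines CCL20 and CXCL8 rose 2.92-fold (1.55 ± 0.081) and 2.79-fold (1.48 ± 0.090), the NF-kappaB subunit RELB by 1.14 ± 0.12 and IL1A by 0.99 ± 0.074. CCL20 was dim, at mean levels of 5.43 in DMSO and 6.97 with docetaxel, which leaves the size of its rise less certain. A dimmer probe set of ATF3 went the other way at -0.49, as did one of IL1A at -0.41. Camera's adjusted p was 2.71e-09 and 3.24e-07, and both lists had adjusted p = 0.54 with an estimated correlation. Interferon-stimulated genes split, with 10 of 25 higher and 10 lower (13 and 11 adjusted over the list alone), a median of 0.30, a mean of 0.064 and an adjusted p of 0.0622. IFI44 fell by 1.70 ± 0.087, while ISG20 rose by 1.63 ± 0.10, OAS1 by 1.22 ± 0.084 and OASL by 0.97 ± 0.11. This list passed the threshold among genes above the median level (adjusted p = 0.0423, with a median of -0.0079), without DMSO replicate 1 (0.0272), without docetaxel replicate 1 (0.0400) and against random lists matched on level (0.000675). Its median was -0.036 without _x_at and _s_at probe sets, where IFI44 was at -0.82, and 11 to 13 members were higher and 6 lower after the other scalings.

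Targets of SRF and genes of the actin cytoskeleton had 9 of 20 members higher and 5 lower, also adjusted over the list alone, and 9 to 11 higher and 2 to 3 lower under the other scalings, with a median of 0.15 and a camera adjusted p of 0.0126. This list had adjusted p = 0.54 with an estimated correlation, and it was not past the threshold after spike-in centring (adjusted p = 0.0555, or 0.0607 with the r2 set) or in fry's directional test (0.0654). The smooth muscle actin ACTA2 rose by 1.0 ± 0.17, the small GTPase RHOB by 0.84 ± 0.072, FHL2 by 0.78 ± 0.080 and TRIB1 by 0.70 ± 0.071. ACTA2 was not called without DMSO replicate 1 (adjusted p = 0.0606) or DMSO replicate 2 (0.0546), and RHOB was not called with the mean of its probe sets, at 0.16. That mean was 0.34 for ACTA2 and 0.19 for TRIB1. Among 19 YAP/TEAD targets 8 rose and 5 fell (8 and 6 adjusted over the list alone; median 0.10, adjusted p 0.0659), and this list passed the threshold after quantile normalisation (adjusted p = 0.0317), without _x_at and _s_at probe sets (0.0186), among genes above the median level (0.0153), with a variance trend (0.0470) and against random lists matched on level (0.00457). Under each other scaling 10 YAP/TEAD targets were higher and 3 lower. The growth factor gene CCN2 rose by 1.13 ± 0.066 and TGFB2 by 0.78 ± 0.088, while the receptor kinase AXL fell by 1.23 ± 0.071 and AJUBA by 0.92 ± 0.089.

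Most chaperone, antioxidant and mitochondrial genes on the lists fell. In the heat shock list 14 of 15 members fell (15 adjusted over the list alone), with a median of -0.58. The co-chaperones DNAJB4, DNAJB1 and DNAJA1 fell by 1.60 ± 0.075, 1.14 ± 0.076 and 0.70 ± 0.071, and HSPA4L by 1.16 ± 0.094. Of 18 NRF2 targets 16 fell, also adjusted over the list alone, with a median of -0.56. The aldo-keto reductases AKR1B10 and AKR1C3 fell by 1.14 ± 0.15 and 1.01 ± 0.079, the glutathione synthesis subunit GCLM by 1.02 ± 0.080 and TALDO1 of the pentose phosphate pathway by 0.79 ± 0.068. Camera's adjusted p was 5.38e-05 for heat shock and 3.68e-05 for NRF2 targets, and both lists had adjusted p = 0.54 with an estimated correlation. Of 25 oxidative phosphorylation genes 22 fell, also adjusted over the list alone, with a median of -0.41 and a camera adjusted p of 5.09e-05. The last list had adjusted p = 0.59 with an estimated correlation. NDUFS3, NDUFB3 and NDUFA9 of complex I fell by 0.73 ± 0.066, 0.63 ± 0.069 and 0.57 ± 0.071, and SDHA of complex II by 0.66 ± 0.066. Random lists matched on mean level had a median of -0.25 (95% between -0.42 and -0.10), and against them the oxidative phosphorylation genes were not past the threshold (adjusted p = 0.111). After quantile normalisation 13 of these 25 genes were called lower and 1 higher.

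Cytoplasmic ribosomal protein genes, among the brightest on the array, had 3 of 22 members lower (0 adjusted over the list alone), with a median of -0.098 and an adjusted p of 0.550. Their counts turned to 8 higher and 0 lower after quantile normalisation, 1 and 0 after median centring and 3 and 0 after either spike-in centring. After quantile normalisation the list was past the threshold in the other direction, with a median of 0.12 (adjusted p = 0.010), and it was higher than random lists matched on level (adjusted p = 0.0436). The members called lower as deposited were RPL8 (-0.24 ± 0.072), RPL7 (-0.23 ± 0.069) and RPL35 (-0.21 ± 0.065). None of the 3 was called after median or spike-in centring or without docetaxel replicate 1, docetaxel replicate 2 or DMSO replicate 2; without DMSO replicate 1, RPL7 and RPL35 were not called. After quantile normalisation none was called and RPL35 was at 0.018. Hypoxia and glycolysis genes were divided, with 6 of 25 higher and 12 lower (6 and 13 adjusted over the list alone). NDRG1 rose by 1.95 ± 0.071, the angiogenic factor VEGFA by 1.58 ± 0.084 and ALDOC by 1.12 ± 0.077, and the enolase ENO2 fell by 1.0 ± 0.071. The median was -0.21 and the mean -0.015, camera placed the list higher at an adjusted p of 0.809, and the median was 0.04 after quantile normalisation. The counts were 9 higher and 6 lower after quantile normalisation, 8 and 8 after median centring and 9 and 8 after either spike-in centring.

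**Figure D3:**
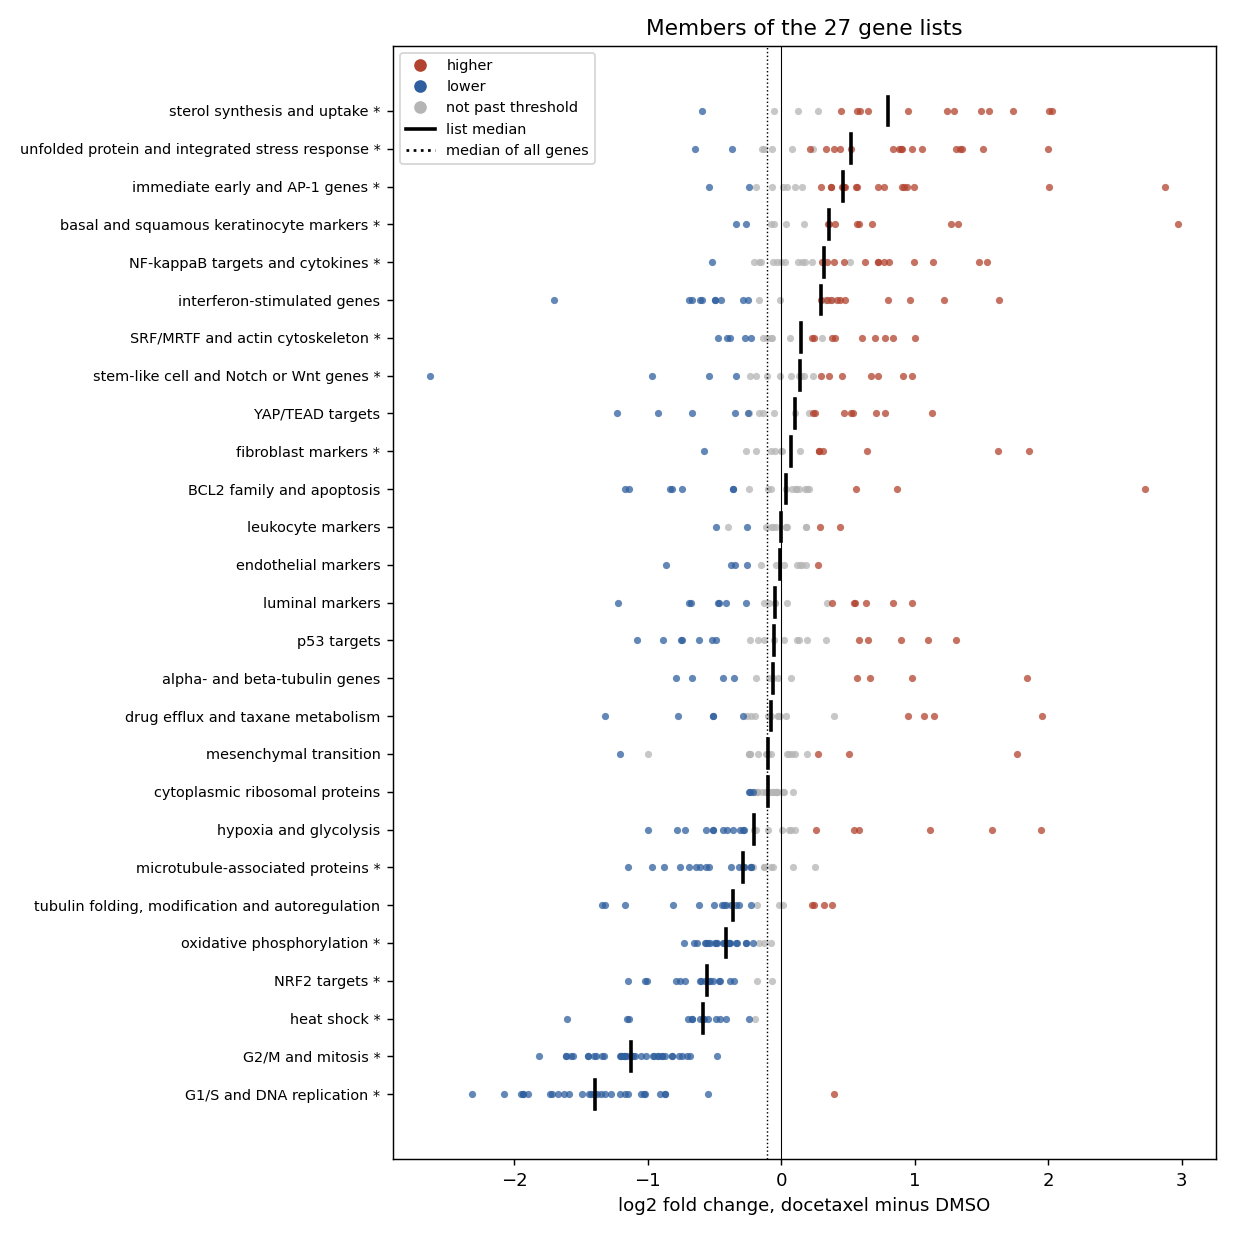
Log2 change (docetaxel minus DMSO, horizontal axis) of each measured member of the 27 gene lists (vertical axis), coloured by call, with a bar at each list's median and a dotted line at the median of all genes, -0.11; an asterisk marks lists past the threshold in camera with the preset correlation. The medians run from -1.39 (G1/S and DNA replication) to 0.80 (sterol synthesis and uptake).

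Most keratinocyte markers rose. Of 15 basal and squamous keratinocyte markers 9 rose and 2, S100A2 (-0.34) and SFN (-0.26), fell, also adjusted over the list alone, with a median of 0.36 and a camera adjusted p of 0.000104. This list had adjusted p = 0.54 with an estimated correlation. S100A2 and SFN were chosen after their values were seen, and after quantile normalisation or centring on the r2 spike-ins 0 members were called lower. SPRR1A and involucrin (IVL), precursors of the cornified envelope, rose by 2.97 ± 0.095 and 1.32 ± 0.19, the desmosomal cadherin DSG3 by 1.27 ± 0.092 and the laminin chain LAMB3 by 0.68 ± 0.088. Luminal markers were split, with 6 of 19 higher and 7 lower (7 and 7 adjusted over the list alone; adjusted p = 0.264). FOXA1 fell by 1.22 ± 0.15 and ESR1 by 0.69 ± 0.077, while MUC1 rose by 0.98 ± 0.065 and XBP1 by 0.84 ± 0.070. ESR1 was not called with the mean of its 9 probe sets, at -0.035, and XBP1 was at 0.38 with the mean of its probe sets. The luminal median was -0.046 and its mean -0.010, camera placed the list higher, and the median was above 0 after each other scaling (0.067 to 0.15), with 6 to 8 higher and 5 to 6 lower.

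Of 20 genes tied to stem-like cells, Notch or Wnt, 7 rose and 4 fell (8 and 5 adjusted over the list alone; 9 to 11 higher and 2 to 3 lower under the other scalings), with a median of 0.14 and a camera adjusted p of 0.0233. For this set, adjusted p = 0.54 with an estimated correlation, and it was not past the threshold after median centring (adjusted p = 0.0535), after spike-in centring (0.0751, or 0.0892 with the r2 set), without docetaxel replicate 1 (0.0694) or without docetaxel replicate 2. Other choices of probe sets (adjusted p = 0.073 and 0.522) and fry's directional test (0.113) also left it short. SOX2 fell by 2.63 ± 0.095 and HEY1 by 0.97 ± 0.075, and ALDH1A1 rose by 0.98 ± 0.085 and SOX9 by 0.91 ± 0.076. In the mesenchymal transition list 3 of 19 members rose and 1 fell, also adjusted over the list alone (median -0.095, adjusted p = 0.423). The matrix protein TNC rose by 1.76 ± 0.076, SNAI2 by 0.51 ± 0.085 and MMP2 by 0.27 ± 0.065, and TWIST1 fell by 1.2 ± 0.075. One dimmer probe set of TNC went the other way at -0.42, and the mean of its probe sets was 0.35. MMP2 was not called with the mean of its probe sets, at 0.034, without DMSO replicate 1 (adjusted p = 0.0606), without docetaxel replicate 1 (0.0732) or without docetaxel replicate 2 (0.0696). Camera placed the mesenchymal list higher although its median and its mean (-0.036) were below 0, and its median was above 0 after the other scalings (0.018 to 0.10), with 3 to 5 higher and 1 lower.

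Drug efflux, p53 and BCL2 family lists were mixed. The drug pump ABCB1 rose 3.88-fold (1.95 ± 0.097), ABCC3 rose by 1.14 ± 0.066 and the oxidase CYP1A1 by 1.07 ± 0.071, while the pump ABCG2 fell by 1.32 ± 0.12. Without _x_at and _s_at probe sets ABCC3 was not called, at 0.053. In that list 4 of 19 members rose and 5 fell (5 and 7 adjusted over the list alone), with a median of -0.080, a mean of 0.065 and an adjusted p of 0.423; its median was 0.028 to 0.12 after the other scalings, with 5 higher and 4 lower. Of 21 p53 targets 5 rose and 7 fell (7 and 8 adjusted over the list alone). SESN2 rose by 1.31 ± 0.069, the cyclin-dependent kinase inhibitor CDKN1A by 1.10 ± 0.066 and the death receptor TNFRSF10B by 0.89 ± 0.069, and DDB2 fell by 1.08 ± 0.066. The p53 list's median was -0.057 and its mean -0.016, camera placed it higher at an adjusted p of 0.405, and its median was 0.056 to 0.15 after the other scalings, with 9 to 10 higher and 6 to 7 lower. Of 21 BCL2 family and apoptosis genes 3 rose and 7 fell (5 and 8 adjusted over the list alone; median 0.034, mean -0.030, adjusted p = 0.423), though against random lists matched on level the list was higher (adjusted p = 0.0479). Its counts turned to 9 higher and 5 lower after quantile normalisation and either spike-in centring, with medians of 0.21 to 0.23, and to 7 and 7 after median centring. BCL2A1 rose by 2.72 ± 0.12 from 2.94, a background level that leaves the size of the change uncertain, to 5.66, BIK rose by 0.87 ± 0.066, and BIRC5 and BCL2 fell by 1.17 ± 0.066 and 1.14 ± 0.081. BIRC5 is also a member of the G2/M and mitosis list. None of the 3 other BCL2 probe sets was called (-0.21 to 0.050), and the mean of its probe sets was -0.33; for TNFRSF10B that mean was 0.43 and for ABCC3 and ABCB1 0.35 and 1.28.

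Markers of other cell types changed in part. No leukocyte or endothelial marker reached the median level of all genes, 7.24. Among 14 leukocyte markers, FCER1G (0.44 ± 0.089) and LYZ (0.29 ± 0.067) rose and CD14 (-0.49 ± 0.13) and CORO1A (-0.26 ± 0.067) fell, also adjusted over the list alone (adjusted p = 0.295 for the list). Among 12 endothelial markers 4 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.467), including KDR (-0.86 ± 0.15), ESAM (-0.38 ± 0.077) and ERG (-0.34 ± 0.10) lower and TEK (0.27 ± 0.065) higher. Of these, CORO1A and TEK were not called when any 1 array was left out, and CD14, LYZ and ERG were not called when some were, with adjusted p up to 0.0946 for CORO1A without docetaxel replicate 1 and up to 0.175 for ERG without DMSO replicate 1. FCER1G was not called with the mean of its probe sets, at 0.10. Both lists were placed higher by camera with medians of -0.0010 and -0.0091 and means of -0.016 and -0.095, and their medians were above 0 after the other scalings. After centring on the r2 spike-ins 7 leukocyte markers were higher and 0 lower, and 4 endothelial markers were higher and 1 lower; with all 18 spike-ins these counts were 6 and 0, and 4 and 2. After quantile normalisation they were 2 and 0, and 2 and 2, and after median centring 2 and 0, and 3 and 2. Of 14 fibroblast markers 6 rose and 1 fell, also adjusted over the list alone, with a median of 0.075 and a camera adjusted p of 0.0151. That list had adjusted p = 0.54 with an estimated correlation, and it was not past the threshold after quantile normalisation (adjusted p = 0.123), after centring on the r2 spike-ins (0.0545), with other choices of probe sets (0.0683 and 0.256), in fry's directional test (0.0698) or against random lists matched on level (0.127). Among genes above the median level, where its dim members drop out, the list's median was 1.63, the change of COL1A1 itself. LUM passed that filter through its docetaxel level alone (6.30 in DMSO, 8.16 with docetaxel). That median is therefore no support for a rise of the list. LUM rose by 1.86 ± 0.21, COL1A1 by 1.63 ± 0.11 and FBLN1 by 0.64 ± 0.069, and FBN1 fell by 0.57 ± 0.065. Without _x_at and _s_at probe sets LUM, at -0.046, and FBN1, at -0.16, were not called, and 1 other probe set each of COL1A1 (-0.28) and FBLN1 (-0.36) went the other way. COL1A1 was at 0.55 with the mean of its probe sets.

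In all, 14 of the 27 lists passed the threshold in camera with the preset correlation, 8 higher and 6 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.54. With 2 residual degrees of freedom that version could hardly pass any list, so it does not decide whether these lists shifted. Even the G2/M and mitosis list, with all 38 members lower, had an unadjusted camera p of 0.18 there. The 3-prime minus 5-prime difference of the control probe sets was 1.10 in DMSO and 0.985 with docetaxel for ACTB, and 0.029 and 0.031 for GAPDH.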

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

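Probe sets without 1 gene symbol were left out of the comparison, and they are given here because they hold a signal outside the tested genes. Some were above the level in DMSO with docetaxel, and more were below it. Of the 11721 probe sets not listed with a gene, 637 were higher and 1094 lower with docetaxel (limma, Benjamini-Hochberg over all probe sets without 1 symbol), and 75 and 91 of these changed at least 2-fold. Of the 1801 with several gene symbols, 137 were higher and 344 lower. The largest rises among those not listed with a gene had log2 changes of 2.73 ± 0.093 (SE, n = 2 arrays per group; limma adjusted p = 4.34e-05) and 2.49 ± 0.097 (limma adjusted p = 6.95e-05). The first was dim in DMSO and reached 5.77 and 5.73 on the docetaxel arrays. The largest falls had log2 changes of -2.24 ± 0.10 (limma adjusted p = 0.000164) and -1.94 ± 0.096 (limma adjusted p = 0.000199). All 4 are unnamed here. These probe sets were tested on the deposited scale alone.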

How the results depend on the processing

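The spike-in centrings and the matched random lists were chosen after seeing the data; the other alternatives were planned. Of 136 named genes, 109 kept their direction and call under every alternative in which they were tested, and 124 did so under the 4 other scalings; 0 of the genes called as deposited was called in the opposite direction under these scalings. Without _x_at and _s_at probe sets 55 were, and with the mean of a gene's probe sets 13. Of the 14 lists past the threshold, 10 stayed past it under every camera and fry alternative but the estimated correlation, and 1 of these 10, oxidative phosphorylation, was not past it against matched random lists.

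The count of genes that rose was 4096 after quantile normalisation, 3718 after median centring, 4880 after centring on 18 spike-in probe sets and 5336 on the 9 of the r2 design, against 2299 as deposited. Genes that fell numbered 4120, 4744, 4006 and 3810 in the same order, against 6340. The centrings move whole arrays against each other, while quantile normalisation also reshapes the levels within each array. Testing every probe set gave 4142 higher and 11763 lower, from more features tested. A fold change of at least 1.5 left 792 and 2267, and treat against 1.2-fold left 922 and 2850, as stricter thresholds do. Leaving out 1 array gave 1578 to 2103 higher and 4541 to 5624 lower, and 13 to 15 lists; the lone array left in a group was assumed to vary like the others. The estimated correlation left 0 lists and fry's mixed test called 27, which asks a different question. Against matched random lists 15 passed, 11 of the 14 and 4 others (interferon, YAP/TEAD, BCL2 family and ribosomal protein lists).

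Values called as deposited that changed sign, or called only with the other sign, were the ribosomal protein list (0.12) and RPL35 (0.018), TUBB3 (0.18) and TUBB4B (0.21) after quantile normalisation; IL1A (-0.41), RPL7 (0.18) and LUM (-0.046) without _x_at and _s_at probe sets, where another probe set stands for the gene; TEK (-5e-04) with the mean of its probe sets; and TUBB1 (0.17) after centring on the r2 spike-ins. The medians of the stem-like (-0.010) and fibroblast (-0.0010) lists also crossed 0 without _x_at and _s_at probe sets, as did medians of uncalled lists under other scalings. Beyond these constructions the cause was not tested.

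With the replicate block, 2190 genes were higher, 6094 lower and 14 lists past the threshold. The replicate differences of the 2 groups correlated at -9e-04 across genes, so the numbers gave no sign of pairing. RPL8, RPL7 and RPL35 were not called with the block, and no other named gene or list changed its call.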

Other observations

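Another 6 gene lists were written after the largest gene changes and the fixed lists' results had been seen, and before these 6 were tested; the tests on spike-ins, RNA quality, mitotic build-up and exchanged arrays were chosen after the result was seen, and so was the interval used for the bright spike-ins. Most DNA repair genes on their list fell with docetaxel. Of 23 measured members of the DNA repair and Fanconi anemia list 19 fell (20 adjusted over the list alone) and 0 rose, with a median log2 change of -1.12, or -1.02 less the median of all genes (camera adjusted p = 1.85e-08 over the 6 lists; adjusted p = 0.48 with an estimated correlation). The Fanconi genes FANCM, FANCI and FANCG fell by 1.81 ± 0.068, 1.64 ± 0.070 and 1.63 ± 0.072 (log2 ± SE), and RAD54L, a recombination factor, by 1.81 ± 0.064, while WRN, at -0.012, did not pass the threshold; these genes were chosen after their values were seen. The falls of replication genes had been seen when this list was written.

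Keratinocyte differentiation genes were placed higher, 0.19 above the median of all genes, with 15 of 40 members higher and 7 lower, also adjusted over the list alone, and 17 to 23 higher and 2 to 5 lower under the other scalings (camera adjusted p = 0.000154; adjusted p = 0.48 with an estimated correlation). The dim SPRR2B rose by 1.38, GRHL3 by 1.04 and KRT13 by 0.98, while KRT80 fell by 1.30 and KLK6 by 0.80, chosen after their values were seen. The other 18 members were not past the threshold, among them FLG (-6e-04), KRT1 (0.0097), KRT10 (0.021) and LORICRIN (-0.16), chosen in the same way. MAPK feedback and output genes had been predicted to fall and went the other way, 0.48 above the median of all genes, with 12 of 20 higher and 4 lower (13 and 4 adjusted over the list alone, 13 to 14 and 1 to 3 under the other scalings; camera adjusted p = 3.62e-05). For that list, adjusted p = 0.48 with an estimated correlation, and 8 of its 20 members also stand in the fixed lists; without them camera's adjusted p was 0.0108. MAFF rose by 1.33 and PHLDA1 by 0.80, likewise chosen after their values were seen. FOXO target and quiescence genes were placed 0.14 above the median of all genes, with 9 of 23 higher and 7 lower, also adjusted over the list alone, and 9 to 12 higher and 6 to 7 lower under the other scalings (camera adjusted p = 0.0443; adjusted p = 0.49 with an estimated correlation), and the 95% bootstrap interval of that difference, -0.030 to 0.50, included 0. Neither MYC target and ribosome biogenesis genes (-0.084 against all genes, adjusted p = 0.265; median -0.19 as deposited and 0.039 after quantile normalisation) nor glucocorticoid targets (0.13, adjusted p = 0.150) passed the threshold, and the predictions for these lists stay undecided. MYC targets had 1 member higher and 11 lower of 25 (1 and 13 adjusted over the list alone), but 11 higher and 4 lower after quantile normalisation, 2 and 7 after median centring, 6 and 6 after spike-in centring and 8 and 6 with the r2 set. The glucocorticoid targets had 5 higher and 4 lower of 15, also adjusted over the list alone, and 6 higher and 3 to 4 lower under the other scalings.

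More genes fell than rose with docetaxel, and an offset between arrays left by the normalisation may account for that excess. The 18 hybridisation spike-in probe sets, added in equal amounts by design, were lower on the docetaxel arrays by a mean of -0.18 (SD 0.12 over probe sets), and after centring on them 45.1% of called genes were lower, against 73.4% as deposited (41.7% with the 9 probe sets of the r2 design, the first choice). The dim bioB spike-ins changed by a mean of -0.21, but the 4495 genes at their level by a median of -0.045. Centring on the spike-ins thus moved such dim genes above 0 on balance, and 45.1% may be too low a share. A weaker response of bright probe sets on the docetaxel arrays stays open: genes at the level of the bright cre spike-ins changed by a median of -0.21 and those at the level of the dim bioB ones by -0.045, a difference of -0.17, while cre minus bioB itself was 0.039 (95% interval -0.17 to 0.24). By the bound set first for this test, a difference above -0.2 by more than 1 SE (0.080), the explanation was argued against, and the interval that replaced it only just reaches the genes' difference (-0.1665 against -0.1658). Spike-ins added at hybridisation do not measure RNA per cell, and a broad effect of docetaxel stays open.

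Mitosis and replication genes fell by far more than such an offset. After spike-in centring the median of both lists' members was still -1.01, and the 3-prime minus 5-prime difference of ACTB and GAPDH was higher with docetaxel by at most 0.0026, which argues against poorer RNA. The 2 splits that exchange 1 array of each group called 0 genes. The G2/M members' median after spike-in centring was -0.95, which argues only against a build-up of mitotic cells with raised G2/M transcripts. A build-up with these transcripts lowered cannot be told apart from no build-up, since these data hold no measure of cell cycle phase. An effect of docetaxel on these genes stays open and untested as to mechanism, and an exchange of the labels of the groups as a whole and a separate batch for each group were not tested.

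The labels' split was 1 of 3 splits of the 4 arrays, it called 8639 genes, and the highest of the others called 0 (35 and 41 genes at an unadjusted p under 0.05 in limma), but 3 splits cannot give a share under 0.05. Both docetaxel arrays lay beyond both DMSO arrays in 71.5% of genes, against 33.3% by chance for 1 gene taken alone. All genes share the same 4 arrays and any offset between them, so 33.3% is no reference for that share. Of the 11136 genes not past the threshold, 5501 were apart in this way too.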
